A study of Mus musculus with 8 samples.

How the data were processed

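RNA from Ly6G-positive bone marrow cells of 4 WT and 4 ATF3 KO samples was labelled with Cy3 and hybridised to single-colour Agilent mouse arrays, per the labels' protocols. Each array was scanned and quantified with Agilent Feature Extraction, version 10.9.1.1 per the file headers and 10.10 per the submitters' processing notes. The deposited scanner files hold spot intensity on a linear scale. Per the file headers, the processed signal intensity is background-subtracted and spatially detrended within each array, and no scaling between arrays is recorded there. The deposited table of the whole series holds values on a log2 scale, whose scale, centring and direction are not stated. Set against the scanner files, each column correlated best with its own array's log2 median signal (r from 0.998 to 1 across features), with column medians from 6.15 to 6.17. It therefore looks like a between-array normalized log2 of the signal without background subtraction, and it was used only as an alternative. Groups and replicate numbers were taken from the sample titles. The description field disagrees with the design text on whether 7 of the 8 samples were cultured, and this was not resolved.

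Control spots and spots with a non-uniformity or population outlier flag were left out, from 98 to 159 spots per array. The spots of a probe were averaged. The log2 processed signal was taken minus each array's 75th percentile over all 55681 probes, since 50.02% of probe values were above background. A probe was kept when it was above background on at least 4 of the 8 arrays, whatever their group (27945 probes), and the probe with the highest mean over all arrays stood for each gene. The files carry no gene symbol column. Symbols came from matching RefSeq transcript accessions, without versions, to a table of GRCm38.p6 genes. A symbol was found for 27235 probes and not for 28446, so 13079 of the 21236 genes tested have one, and the rest keep the accession of the file. Because the headers name another build, no coordinates of that table are given, and it served only for names and for which genes lie near each other.

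Differences between ATF3 KO and WT were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, genotype as the only term), with Benjamini-Hochberg adjusted p under 0.05. Of 28 gene lists, 27 were tested with camera at a preset correlation of 0.01, and the list of sex-linked genes was only described. A list's score in an array is the mean deviation of its members from their own means over the 8 arrays, relative to the median of all genes. Scores and array measures were compared by two-sided exact permutation tests. Genes near Atf3 were tested with a one-sided Fisher's exact test in a window of 25 Mb on either side. A gene not above background on any array of a group has only a bound on its fold. The rule for the genes named was fixed before the data were examined. Atf3, and Tiam2 from knowledge of the study, are given whatever their values. Then come, among called gene symbols above background in both groups with separated groups, the 12 largest rises and the 12 largest falls (10 met the rule), up to 4 by the size of the bound among called genes above background in 1 group only, up to 4 members with the smallest p from each list, and up to 8 called genes in the window around Atf3.

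On simulated data with the real means and spreads of the 21236 genes and 200 genes changed, the limma step recovered 40% of genes changed 1.5-fold, 76% changed 2-fold, 96% changed 4-fold and 100% changed 8-fold. Of 165 calls, 9 were false. The simulation has independent genes, so it does not test camera's calibration under correlated genes. No 2 arrays held identical values, and the smallest root mean square difference was 0.282 between WT arrays and 0.401 between ATF3 KO arrays on the log2 scale, so each array counts as 1 sample. The number of arrays limits the precision.

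The alternatives were normexp background correction (offset 50), quantile normalization, median scaling, the percentile over detected probes, other filters on dim probes, every probe tested, other variance models, array weights, the replicate number as a block, the deposited log2 table, leaving out each array, an estimated correlation, fry, an adjusted p under 0.1, a minimum fold of 1.5 and windows of 10 and 50 Mb. The normexp alternative was planned on the mean signal. The scanner files used here have no such column, and the median signal took its place. The results of 1 gene list, with an alternative for it added after seeing the data, and of 2 genes named by the rule are not reported here, though counts include them. A fit without the 2 ATF3 KO arrays with the highest platelet scores was also run. It was dropped and its values are not reported, because it chose arrays by the outcome, and the megakaryocyte and platelet call did not hold in it.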

Results

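Gene expression was measured in neutrophils from the bone marrow of wild-type (WT) mice and of mice lacking ATF3, a stress-induced transcription factor of the ATF/CREB family. Both were on a C57BL/6 background. The neutrophils were taken as the fraction carrying Ly6G, a neutrophil surface protein, by magnetic bead sorting, and their RNA was hybridised to 8 single-colour Agilent arrays, 4 per genotype. The series title places the comparison in the study of neutrophil migration. The design text has RNA isolated directly after sorting, whereas the description field of 7 samples mentions culture in methylcellulose, so the labels conflict on this point. Nothing in the labels says that the samples came from separate animals, and the p-values then measure only the spread between these samples. All 8 arrays lay on 1 slide and were scanned together, with the WT samples in one row of the slide and the ATF3 KO samples in the other, so slide row and genotype cannot be told apart.

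The 75th percentile of the processed signal was 215 ± 41.0 in WT and 159 ± 24.0 in ATF3 KO arrays (SD, n = 4, two-sided exact permutation p = 0.0857). The share of probes above background was 51.0 ± 3.66% in WT and 49.1 ± 3.29% in ATF3 KO (exact permutation p = 0.486). No spot was saturated. Correlations between arrays, taken across genes, ran from 0.991 to 0.996 within WT, from 0.986 to 0.992 within ATF3 KO and from 0.981 to 0.992 between the groups. The number of arrays limits the precision of every value.

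The probe for Atf3, the deleted gene, gave a higher and not a lower signal in the ATF3 KO samples. Its log2 signal relative to the array's 75th percentile was 0.73 ± 0.07 in WT and 1.24 ± 0.27 in ATF3 KO (SD, n = 4). The log2 difference of 0.51 (SE 0.14) did not pass limma's threshold (adjusted p = 0.12), although all 4 ATF3 KO arrays lay above all 4 WT arrays (exact permutation p = 0.0286, the smallest that 4 against 4 allows). With the deposited log2 table it passed (0.54, limma adjusted p = 0.0344, the lowest of a range up to 0.316 over the alternatives). The array has 1 named probe for this gene, and whether it lies inside the deleted part is not known from the sources used here. If it lies outside, it checks nothing, so the genotype labels were not verified by this probe.

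Tiam2, which encodes an exchange factor that activates the GTPase Rac, gave the largest difference among the named genes. Its log2 signal was 3.59 ± 0.07 in WT, where it was above background on all 4 arrays, and it was not well above background on any ATF3 KO array (measured mean −4.56 ± 0.38, SD, n = 4). The bound on its fold, WT over ATF3 KO, was 103. This bound sets the WT mean against the mean, over the ATF3 KO arrays, of the lowest signal among probes above background or the probe's own if higher. It is not a strict lower limit, since a probe can lie over that lowest signal and still not count as above background. The limma adjusted p was 3.43e-08. The bound holds for the background-subtracted signal, and the measured log2 difference of −8.15 was −4.50 with normexp background correction and −4.84 with the deposited log2 table. Tiam2 is on chromosome 17, and 1 probe was named for it.

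**Figure D1:**
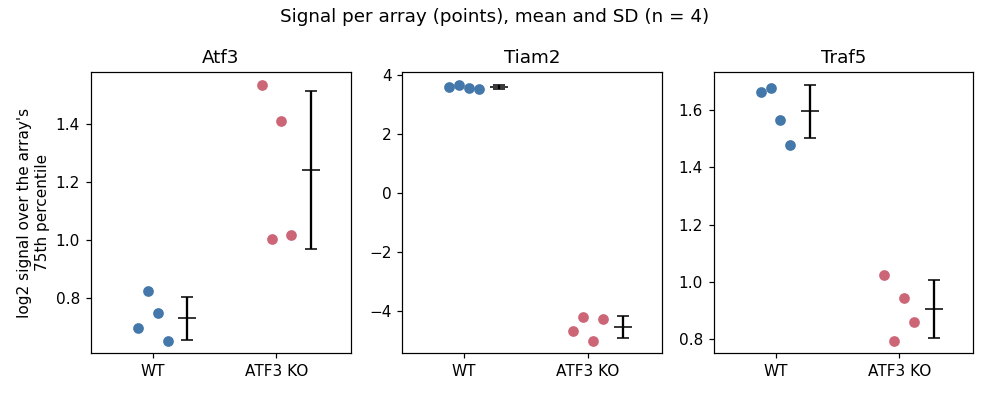
Log2 signal of Atf3, Tiam2 and Traf5 relative to each array's 75th percentile (vertical axes) in the WT and ATF3 KO samples, with 1 point per array and the mean and SD beside them (n = 4). Tiam2 lies near 3.59 in WT and near −4.56, not well above background, in ATF3 KO, and the Atf3 probe is higher in all 4 ATF3 KO arrays.

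Of 21236 genes tested, 95 passed the threshold, 78 of them higher and 17 lower in the ATF3 KO samples. A gene symbol other than a RIKEN, Gm or LOC name could be given to 27 of the 95, of which 15 rose and 12 fell, and 1 more that rose had such a name. The largest named rises among genes above background on at least 1 array of each group were those of Magi1, a scaffold protein of cell junctions (log2 difference 1.49, SE 0.25), Acvr2b, an activin receptor (1.45, SE 0.24), and the homeobox gene Hoxb9 (1.41, SE 0.16). Psapl1 (1.33), Susd4 (1.28), the methyltransferase gene Bhmt (1.27), Derl3 (1.12) and the collagen gene Col25a1 (0.99) followed. Ccr7, a chemokine receptor of lymphocytes and dendritic cells, rose by 0.94 (SE 0.16), and Amer1 (0.89), Pipox (0.87) and Nppa (0.84) rose less. The adjusted p of these 12 genes lay between 0.0127 and 0.0494. In WT, Hoxb9 was above background on 1 of 4 arrays and Derl3 on 2, so the sizes and ranks of these 2 rises rest partly on signal at background.

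Among the falls of genes above background on at least 1 array of each group, the kinesin gene Kif1a fell by 1.30 (SE 0.19) on the log2 scale, and Aim2, a sensor of cytosolic DNA, fell by 1.01 (SE 0.16). Vsig4, a complement receptor of tissue macrophages, fell by 0.92, Esm1 fell by 0.86, and Me1, the malic enzyme, fell by 0.84. The endothelin receptor gene Ednra fell by 0.78, the lipoprotein lipase gene Lpl fell by 0.74, the TNF receptor adaptor gene Traf5 fell by 0.69, and the carboxylesterase gene Ces1d fell by 0.67. Among the ATF3 KO arrays Kif1a was above background on 1, and Aim2 and Me1 on 2 each, so the sizes of these 3 falls rest partly on signal at background. With normexp they shrank to −0.21 for Kif1a, −0.24 for Aim2 and −0.15 for Me1. Of the 23 genes named for their size, rises included, 15 were over 1.5 times smaller with normexp and 14 with the deposited log2 table, and 0 moved by as much under any other alternative. Asap3 was above background on all 4 WT arrays and on no ATF3 KO array, and the same bound on its fold, WT over ATF3 KO, was 1.68 (limma adjusted p = 0.0054). Its measured log2 difference of −2.39 ran from −2.49 to −0.25 over the 14 alternatives that tested it.

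**Figure D2:**
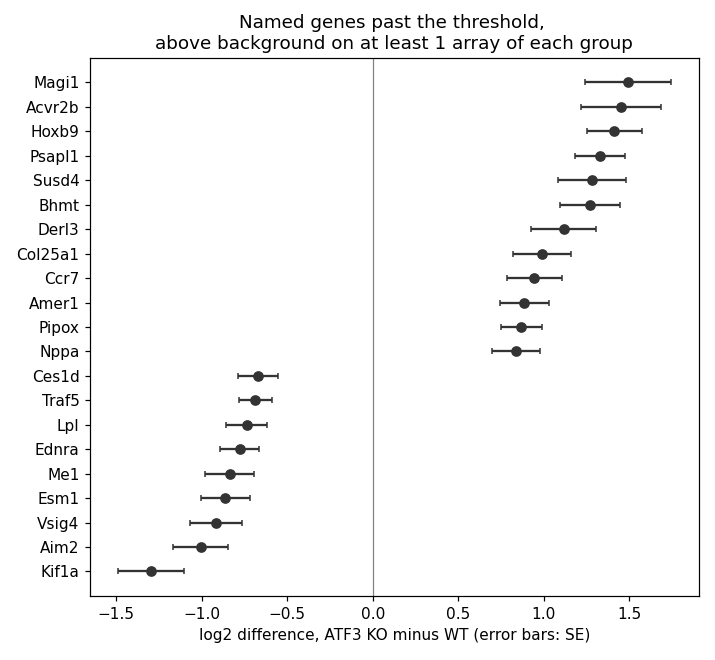
Log2 difference between ATF3 KO and WT samples (horizontal axis, points, with SE as error bars) for genes named in the text that passed the threshold and were above background on at least 1 array of each group. The 12 rises run from 0.84 to 1.49 and the falls from −0.67 to −1.30.

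Most of the remaining calls carry only an accession. Among them were 33 Ensembl transcripts, all higher in ATF3 KO, out of 1381 tested. ENSMUST00000103444 rose by 3.02 and ENSMUST00000103448 by 2.95. The accession NM_133362 fell by 4.59 (SE 0.26) and TC1700876 fell by 4.78 (SE 0.31). These have no name in the tables used here.

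The count of calls depended on the scaling and on single arrays. With the percentile taken over probes detected on all arrays it was 35 higher and 9 lower, and this choice rested on 50.02% of probe values being above background, just over the share at which all probes are used. The call split also moved, to 156 higher and 95 lower with normexp background correction (62.2% higher, against 82.1%) and to 22 higher and 9 lower with quantile normalization (71.0%). The share higher ran from 40%, with no filter on dim probes (4 higher and 6 lower), to 90.7% without WT replicate 4 (49 and 5). Without ATF3 KO replicate 2 it was 52.9% (9 and 8). Without WT replicate 1 or without WT replicate 3, 5 genes passed, and without ATF3 KO replicate 3, 226 did. The count was 32 without WT replicate 2, 54 without WT replicate 4, 17 without ATF3 KO replicate 2 and 28 without ATF3 KO replicate 4. Apart from Tiam2, 23 genes named here for their size had passed, and of the 22 of them that could be tested, 0 passed without WT replicate 3 and 1 without WT replicate 1. With the main scaling the median log2 difference of all genes was −0.11, and the list values below are given relative to it. The 4 values of one group all lay above or all below the 4 of the other for 15.1% of genes, where chance gives 2.86%, and 5079 genes had an unadjusted p under 0.05. In both counts the balance lay the other way from that of the genes past the threshold, with 2324 genes lower and 878 higher among the separated ones and 3085 lower and 1994 higher at an unadjusted p under 0.05.

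Gene lists fixed before the data were examined were compared with all other genes, and 8 of the 27 tested passed camera's threshold. None of the 8 passed with an estimated correlation between genes (lowest adjusted p = 0.90), and 25 of the 35 splits of the 8 arrays into 4 and 4, the real one included, gave as many lists. The list results are therefore given as measured shifts. For 6 lists every array of one group scored above every array of the other (exact permutation p = 0.0286 each, adjusted p = 0.133 over 28 lists). With fry, which tests whether a list's genes move on balance in one direction and does not compare them with other genes, 5 lists passed. Among them were the B lineage and cholesterol metabolism lists (fry adjusted p = 0.0483 each), dendritic cells and MHC class II (0.0494) and the immediate early genes, which did not pass with camera. The stroma (0.0951), megakaryocyte (0.451), interferon (0.695) and eosinophil lists (0.524) did not pass with fry.

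Genes of the B lineage were higher in the ATF3 KO samples. The median of the 18 measured members was 0.67 above that of all genes on the log2 scale, and all 18 lay above it (camera adjusted p = 1.37e-10; adjusted p = 0.90 with an estimated correlation). Adjusted over the list alone, 13 rose, whereas 0 passed limma's threshold over all genes, with 13 at an unadjusted p under 0.05. Jchain, the joining chain of secreted antibodies, differed by 1.81 (SE 0.35), Il7r by 0.91 (SE 0.22) and Mzb1 by 0.74 (SE 0.15). With normexp background correction the list's median was 0.42. Genes of dendritic cells and MHC class II had a median 0.39 above that of all genes (camera adjusted p = 0.000159; adjusted p = 0.90 with an estimated correlation). Adjusted over the list alone 5 of 13 rose, among them Ccr7, Ciita (0.72), Cd74 (0.34) and H2-Eb1 (0.31), and Zbtb46 fell by 0.45. Over all genes only Ccr7 passed, and with normexp the list's median was 0.23.

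Genes of cholesterol metabolism were lower in the ATF3 KO samples. None of the 22 measured members lay above the median of all genes, and the list's median was −0.34 relative to it (camera adjusted p = 2.32e-06; adjusted p = 0.90 with an estimated correlation). Adjusted over the list alone 19 fell, and 0 passed limma's threshold over all genes, with 19 at an unadjusted p under 0.05. The enzyme genes of cholesterol synthesis Fdps (−0.75, SE 0.17), Sqle (−0.74, SE 0.18), Mvk (−0.73, SE 0.16) and Idi1 (−0.57, SE 0.15) had the smallest p-values. Genes of marrow stroma and endothelium were also lower, with a median of −0.15 relative to all genes and 0 of 15 members above it (camera adjusted p = 0.00269; adjusted p = 0.90 with an estimated correlation). Adjusted over the list alone 5 fell, among them the chemokine gene Cxcl12 (−0.69, SE 0.16), Igfbp5 (−0.74, SE 0.15) and the bone matrix gene Ibsp (−0.91, SE 0.25). The list's median was −0.28 without ATF3 KO replicate 4, −0.26 without WT replicate 3, −0.27 with quantile normalization, −0.26 with array weights and −0.24 with no filter on dim probes.

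Other lists rested on few arrays or genes. The megakaryocyte and platelet list had a median 0.72 above that of all genes (camera adjusted p = 0.000253; adjusted p = 0.90 with an estimated correlation), but its score overlapped between groups (exact permutation p = 0.0857), and adjusted over the list alone 1 member rose and 2 fell. Its median was 0.45 without ATF3 KO replicate 4, 0.37 with normexp and 0.445 with the deposited log2 table. The interferon response list was 0.35 above all genes (camera adjusted p = 0.00131; adjusted p = 0.90 with an estimated correlation), with no member past the threshold over all genes or adjusted over the list alone. It was high in ATF3 KO replicate 3 alone, at a score of 1.06, and without that array its adjusted p was 0.989. Its median was 0.21 with normexp. The list of eosinophils, basophils and mast cells was 0.18 above all genes (camera adjusted p = 0.0398; adjusted p = 0.90 with an estimated correlation). Of its members, the transcription factor gene Gata2 (0.75, SE 0.13) passed over all genes but missed the threshold in 15 of 19 alternatives (adjusted p from 0.0324 to 0.168). The list's adjusted p was 0.284 without ATF3 KO replicate 1, 0.127 without WT replicate 2 and 0.0939 without WT replicate 3, and its median was 0.33 without ATF3 KO replicate 3, 0.29 with a filter on all 8 arrays, 0.27 with array weights, 0.10 without WT replicate 2, 0.092 with normexp, 0.086 without ATF3 KO replicate 1, 0.085 with no filter and 0.071 with the deposited table. Its camera call was also lost with normexp, median scaling, the percentile over detected probes, no filter and the deposited table (adjusted p from 0.0526 to 0.149).

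**Figure D3:**
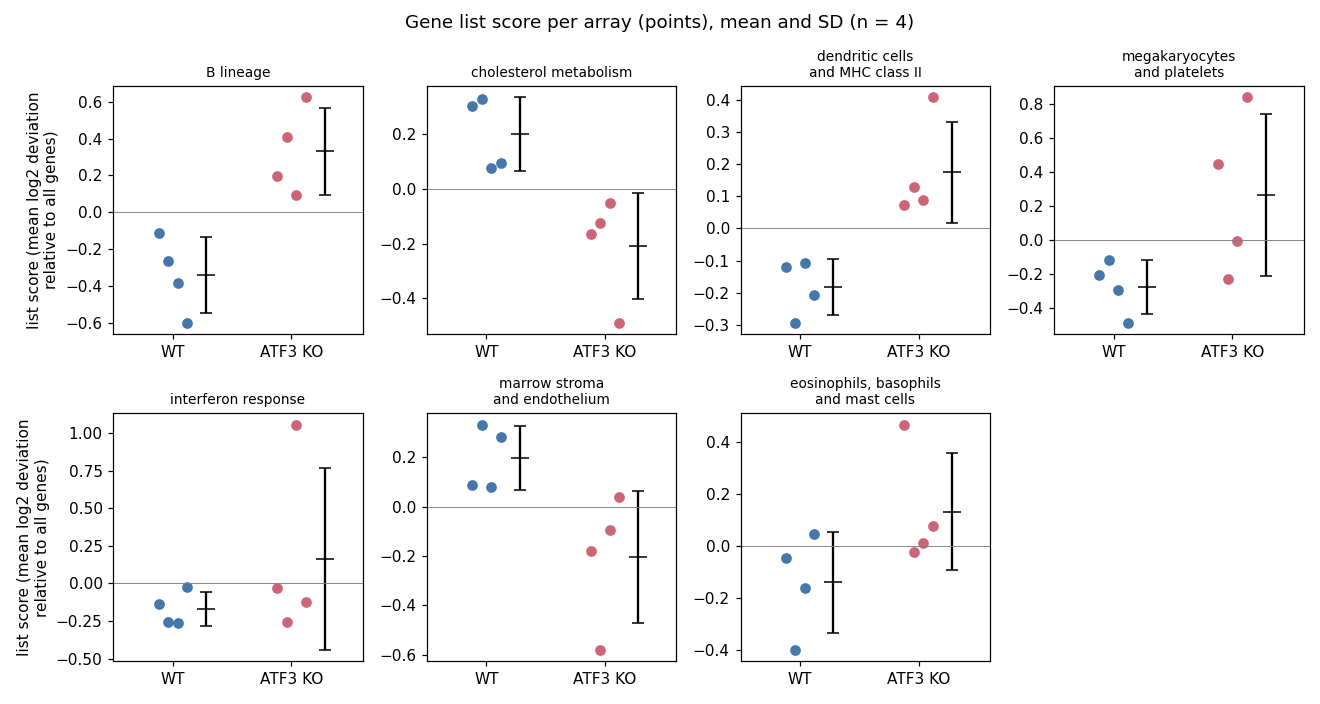
Score in each array of the described gene lists past camera's threshold (vertical axes: mean log2 deviation of the members from their own mean over the 8 arrays, relative to all genes), with 1 point per array and the mean and SD (n = 4). B lineage scores run from −0.60 to −0.11 in WT and from 0.09 to 0.62 in ATF3 KO, and the interferon score is 1.06 in ATF3 KO replicate 3 only.

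The 19 other tested lists did not pass. Receptors for chemoattractants and growth factors had a median of −0.05 relative to all genes (camera adjusted p = 0.399), adhesion molecules −0.06 (0.198) and actin cytoskeleton genes −0.01 (0.61). Adjusted over the list alone, 2 adhesion molecules fell, the integrin genes Itgax (−0.51, SE 0.13) and Itgb3 (−0.46, SE 0.11). Primary granule proteins (0.268), secondary and tertiary granule proteins (0.241), mature neutrophil markers (0.628) and proliferation genes (0.241) did not pass, the bracketed values being camera adjusted p-values. The immediate early genes and AP-1 family (0.145) had a score lower in all 4 ATF3 KO arrays than in any WT array (−0.14, exact permutation p = 0.0286) and a fry adjusted p of 0.0483. They had 4 members that fell adjusted over the list alone, namely Egr1 (−0.81, SE 0.18), Fos (−0.50), Batf3 (−0.51), which also lies near Atf3, and Egr3, which was above background on no ATF3 KO array. The list of inflammatory cytokines and TLR response genes (0.35) had 3, namely Ccl4 (−0.64, SE 0.17), Ccl3 (−0.56) and Ptgs2 (−0.48). The stress lists did not pass either, with 0.7 for the integrated stress and ER stress response, in which Atf6 fell by 0.49 adjusted over the list alone, and 0.969 for heat shock and handling stress. The median of the stress response list and of the ribosomal proteins lay above that of all genes, by 0.015 and 0.045, whereas camera's direction was down. Adjusted p was 0.107 for apoptosis, 0.268 for glycolysis, 0.756 for NADPH oxidase and phagocytosis and 0.789 for ribosomal proteins. Among other cell types it was 0.139 for monocytes and macrophages, 0.399 for T and NK cells, 0.0844 for erythroid cells and 0.399 for stem and progenitor cells. Xist was above background in all 8 arrays, at −1.49 in WT and −1.59 in ATF3 KO.

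Genes past the threshold were more frequent close to Atf3. Within 25 Mb of Atf3 in GRCm38.p6, 3 of 177 named genes passed, against 25 of 12900 elsewhere (odds ratio 8.88, one-sided Fisher's exact p = 0.00623). The 3 were Traf5 and Aim2, which fell, and Susd4, which rose. The number was 0 without WT replicate 1, without WT replicate 3, without ATF3 KO replicate 2 or without ATF3 KO replicate 4. It was also 0 with no filter on dim probes and with the replicate number as a block, and 1 without WT replicate 2. The same test gave a Fisher's exact p of 0.208 with normexp background correction and 0.0763 with median scaling. The number was 6 with trend and robust variances (exact p = 0.000741), 5 with array weights (0.000728), 5 with the deposited log2 table (0.000941) and 9 at an adjusted p under 0.1 (0.001), and with quantile normalization p was 0.000273.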

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

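The splits of the samples were stated before their results were seen, and the window around Atf3 was planned before the data were examined. Chosen only after the result was seen were the tests of the B lineage, of array brightness and scaling, of another strain's sequence beside Atf3 and of the brightness, surroundings and probe of Tiam2.

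Single arrays stood far from the other 3 of their group in 11 of 316 groups of 4 values, where chance gives about 15.8. The score of mature neutrophil markers was −0.11 in WT replicate 1, and that of dendritic cells and MHC class II was 0.41 in ATF3 KO replicate 4 against 0.07 to 0.13 in the others. Log2 signals apart from their group were Esm1 at 1.07 in ATF3 KO replicate 2, Ccnb2 at 4.18 and Bcl2l11 at −3.39 in ATF3 KO replicate 4, and Idi1 at 2.26 and Phgdh at 1.53 in ATF3 KO replicate 3. In ATF3 KO replicate 1 Il5ra was at −0.013. In WT, Phgdh was at 1.66 in replicate 1, and Pgam1 was at 7.62 and Ciita at −1.60 in replicate 2.

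No other split of the 8 arrays gave a gene past the threshold. Of the 35 splits into 4 and 4, 1 gave as many as the 95 genes, the real one, and the highest of the others was 0. A share of 1 in 35 is the smallest that this test can reach. Every other split mixes the genotypes, so a true group difference widens its spread and lowers its count. The real split is also the split by slide row. For gene lists the real split did not stand apart. The real split gave 8 lists, 25 of the 35 splits gave as many, and the highest other gave 18. All splits gave at least 4, so the arrays share structure that does not follow genotype, and camera at the preset correlation calls lists from it. For named genes near Atf3, 1 of the 35 splits, the real one, gave 3, and the highest other gave 0, which follows from those splits having no calls at all.

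The first pattern is the rise of B-lineage genes, none of which is in another list. A lower share of neutrophils that raised every other cell type alike is argued against by the score of marrow stroma and endothelium. That score differed by −0.40 between ATF3 KO and WT. The groups were separated by a narrow margin (0.039 in ATF3 KO replicate 4, 0.080 in WT replicate 3), and the list's median was −0.15 relative to all genes. However, 6 other cell type scores were higher, from 0.13 for T and NK cells to 0.54 for megakaryocytes and platelets. Of these, only that of dendritic cells and MHC class II (0.36) had the groups separated, and whether its rise shares a source with the B-lineage genes was not tested. The stroma score cannot decide about a lower share of neutrophils that let in some cell types and not others. Array brightness and scaling as the whole cause are argued against by normexp, quantile normalization and the deposited table, under which the list's score stayed separated between the groups (highest camera adjusted p 1.61e-07, although camera's p-values are too small here), while its median fell from 0.67 to 0.42 with normexp. B-lineage cells among the sorted cells in varying number remain a candidate explanation, because within the groups each member correlated with the mean of the others (median r 0.75 over 18 genes, reached by 0 of 10000 random lists), but 13 of the 26 other lists had a higher estimated correlation, so the evidence is weak. Among the members with the highest signal, named here for their level, Jchain was at 3.69 in WT and 5.50 in ATF3 KO, Cd79b at 4.53 and 4.86, and Blnk at 4.14 and 4.13, so they did not move alike. Selection for Ly6G is meant to remove such cells, but purity was not measured here, and these members gave signal in both groups. Slide row cannot be told apart from genotype, and a change in the B cells of the marrow by genotype was not tested.

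The second pattern is the set of called named genes near Atf3, which rests on 3 genes and is lost without any of 5 single arrays. A stretch of another strain's sequence left beside the deleted gene could account for it and cannot be told apart from an effect of the deletion on its neighbours. Among named genes that did not pass, which did not define the pattern, 47 of 174 within 25 Mb had an unadjusted p under 0.05 against 3060 of 12876 elsewhere (odds ratio 1.19, one-sided Fisher's exact p = 0.181), too few to decide. Of neighbours singled out after their values were seen, Pacc1 (0.59, limma adjusted p = 0.0532) and Rd3, which was lower (adjusted p = 0.0644), missed the threshold. So did Flvcr1 (−0.39), Ppp2r5a (0.40), Batf3 (−0.51) and Nenf (−0.29), with limma adjusted p from 0.106 to 0.206. All of these had an unadjusted p under 0.05, and all but Nenf had the groups separated. Being picked by their values, they cannot decide between the explanations. Only named genes were placed relative to Atf3, so called intervals without a name, some on chromosome 1 by their labels, were not counted. Among these was a measured log2 difference of −1.80 (limma adjusted p = 0.00235), above background on all 4 WT arrays and on no ATF3 KO array. Another rose by 2.30 (limma adjusted p = 0.0345). Their distance from Atf3 was not measured. An effect of the deletion was not tested.

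The third pattern is the loss of Tiam2 signal, for which dimmer ATF3 KO arrays are argued against, since the WT arrays were 1.35 times as bright and the bound on Tiam2 is 103-fold. A changed stretch of chromosome 17 that reaches genes beside Tiam2 cannot be told apart from an effect on Tiam2 alone, because within 5 Mb 2 of 36 genes had an unadjusted p under 0.01 against 833 of 13041 elsewhere (one-sided Fisher's exact p = 0.679), and the 95% interval of the odds ratio, 0.1 to 3.37, is too wide to decide. Cldn20, singled out beside Tiam2 after its value was seen, was above background on all 4 WT and on no ATF3 KO array (limma adjusted p = 0.0571), whereas Scaf8 (−0.067) and Tfb1m (−0.14) overlapped between the groups. A base difference under the probe also stays open, because the array has 1 named probe of Tiam2. Regulation of Tiam2 by ATF3 was not tested.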

How the results depend on the processing

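The alternatives below were planned. Tiam2 kept its direction and its call in the 14 alternatives that tested it (log2 −8.27 to −4.50, the smallest with normexp). It was not tested when a WT array was left out or when all 8 arrays had to be above background, by construction of the filter. Atf3 stayed between 0.41 and 0.66 and passed only with the deposited log2 table (0.54, adjusted p = 0.0344, range 0.0344 to 0.316). The other 23 named called genes kept their direction wherever they were tested, but 15 were over 1.5 times smaller with normexp and 14 with the deposited table. Over those alternatives they passed in 203 cases and missed the threshold in 224. Gata2, named from a gene list, kept its direction and missed the threshold in 15 of 19. Of the 95 genes, 4 were above background on no ATF3 KO array and 6 on no WT array, so signal over background leaves only a bound on their size. The cause of the changes below was not tested except where stated.

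Genes past the threshold (higher and lower) numbered 251 (156 and 95) with normexp background correction, 31 (22 and 9) with quantile normalization, 217 (176 and 41) with median scaling and 44 (35 and 9) with the percentile over detected probes. They numbered 10 (4 and 6) with no filter on dim probes, where 37057 genes were tested, 58 (44 and 14) with every probe tested, 192 (136 and 56) with trend and robust variances, 148 (112 and 36) with array weights, 149 (109 and 40) with the deposited table and 403 (264 and 139) at an adjusted p under 0.1. Leaving out 1 array gave 5 to 226 genes, 3 to 181 higher and 2 to 45 lower. Fewer samples were tested there, but leaving out ATF3 KO replicate 3 raised the count.

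Same-numbered samples deviated together by correlations of 0.19, −0.13, −0.27 and 0.18, which show no common pairing. They do not decide whether the numbers pair the samples, because the median local background tended to fall with the number in both groups. From number 1 to 4 it was 38.5, 37, 37 and 33 in WT and 39, 37, 36 and 31 in ATF3 KO. Of the WT samples, 1 and 4 correlated best with their own number. With the replicate block, 72 genes passed, 61 higher and 11 lower, 50 of them among the 95, and 0 genes near Atf3 passed.

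Lists past the threshold numbered 15 with normexp, 0 with an estimated correlation (1 list at an unadjusted p under 0.05) and 5 with fry, which does not compare a list with other genes, and 6 to 10 without 1 array. Without ATF3 KO replicate 3 camera's direction for the interferon list turned, its median staying 0.0803 above all genes against up to 0.47 without another array. Named genes near Atf3 past the threshold were 3 with normexp (Fisher's exact p = 0.208) and 3 with median scaling (exact p = 0.0763), 0 with no filter, and 0 to 4 without 1 array. They were 6 with trend and robust variances, 5 with array weights, 5 with the deposited table and 9 at an adjusted p under 0.1 (highest exact p 0.001). With every array above background they were 4 (exact p = 0.00255) and with every probe tested 2 (exact p = 0.0104), and they stayed at 3 with quantile normalization (exact p = 0.000273) and with the percentile over detected probes (exact p = 0.000371). Members that missed the threshold in every setting changed sign, namely Bcl2l11 (0.012, normexp), Camp (−0.0037), Ltf (−0.0403) and Hba-a1 (−0.23) with quantile normalization, and Rpl4 (0.0072) and Xist (0.0528) with the percentile over detected probes. With the deposited table these were Ptafr (0.005), Camp (−0.0275), Ltf (−0.0825), Ccnb2 (0.0375) and Hba-a1 (−0.17), and without 1 array Rhag (−0.0330 to 0.59) and Xist (−0.14 to 0.0036).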

Other observations

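The 33 unnamed Ensembl transcripts that rose in the ATF3 KO samples were tested for whether they come with the B-lineage genes, a hypothesis stated before the result was seen. Within the groups, their median correlation with the B lineage score was −0.0664, and 6794 of 10000 random sets of as many genes reached it. The quartiles of the 33 correlations were −0.201 and 0.137, and 1 was above 0.5, the level set beforehand for a shared source. These values do not decide whether RNA that comes with the B-lineage genes is their source. No gene name was available for the transcripts, so what they encode, which bears on the question, was not examined. A median under 0.2 had been set beforehand as speaking against it, but that level assumed 1 source moving with the B lineage score, whereas 13 correlations lay above 0 and 20 below it, and the transcripts were highest in different ATF3 KO arrays, 12 each in replicates 1 and 2, 7 in replicate 3 and 2 in replicate 4.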
